A study of Mus musculus with 96 samples.

How the data were processed

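The data came from single-cell tagged reverse transcription (STRT), a method that adds a well barcode during reverse transcription and reads the 5′ end of each transcript with its strand. One 96-well plate held 48 wells labelled as mouse embryonic stem cells (ES cells) of the R1 line, 44 wells labelled as mouse embryonic fibroblasts (MEFs) and 4 negative control wells. Per the labels, each well was 1 sample and the whole plate was 1 library, with ES cells and MEFs grown in separate media. The labels give R1 as the source cell line of the MEF wells too, which conflicts with their cell type label, and wells were grouped by cell type. ES cells filled 1 side of the plate and MEFs the other, so plate column and cell type could not be told apart, whereas each of the 8 plate rows held both types. The 4 negative control wells lay on the MEF side.

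The deposited table gave raw read counts per transcript, spike-in RNA and repeat type in each well, with no normalisation by the authors. Per the file headers, reads had their barcode and the Gs added at the 5′ end removed, trailing As were trimmed, and low-quality or short reads were dropped. Bowtie was named as the aligner in the submitters' processing notes, and its version, the genome build and the gene annotation were not given in the sources used here. Per the file headers, the per-well counts were maximum exon hits, which include reads with alternative mappings, gene variants at one locus share counts, and repeat rows hold both strands. A separate column deposited by the authors gave uniquely mapped reads over the whole plate, and another gave transcript length. No molecular identifiers were mentioned per the labels or headers, so PCR copies of one molecule were counted separately.

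The table held 21711 gene rows, 1217 repeat rows and 8 spike-in rows. Of the gene rows, 13973 had a read, 92.7% of gene reads were unique, and 533 rows had under 50% unique reads. Gene, repeat and spike-in reads were totalled apart. All columns of per-well values were mapped to a sample by well position. Cell wells with at least 10000 gene reads entered group values, which kept 45 of 48 ES cell wells and 44 of 44 MEF wells. ES cell replicates 32, 44 and 46 fell below this minimum. No wells held identical values.

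The labels name no separate cultures within a cell type, so each type was treated as 1 culture, cells were not counted as replicates, and no p-value, standard error or count of significant genes was computed. Counts were summed over the cells of a type and divided by the total of gene reads to give counts-per-million values (CPM), and the log2 ratio is ES cell over MEF. A sum of 0 took a floor of 3 reads over the group, which gives a bound. Pooled sums carried exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals at the 95% level. Both cover counting error only, because reads without molecular identifiers are not independent molecules. The size of a difference was set against the SD of the same log2 ratio over the 8 plate rows. As each row held different cells, this spread mixes cell-to-cell and technical variation within the plate. It holds no culture-to-culture variation.

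The following choices were made before the data were examined. Named genes had at least 100 reads and reads in at least 25% of the cells of the higher type. They were the 12 highest and 12 lowest by log2 ratio with 10 CPM added, at least 2-fold the same way in the mean of per-cell CPM and in plate rows A to D and E to H alone. From each gene list, the 4 members with the largest absolute value of that measure were added, with Pou5f1, Nanog, Sox2, Zfp42, Col1a1, Col1a2, Fn1 and Vim always named. The 8 repeat types with the largest value and the 8 most variable genes of each type completed the set, from which 2 genes are not reported here. Other genes, such as Rpl4 and the few exceptions within a list, were named after their values were seen.

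The 22 gene lists covered pluripotency, extracellular matrix, mesenchymal identity, actin cytoskeleton, S phase, G2 and M phase, cell cycle inhibitors, DNA methylation and Polycomb, glycolysis, immediate early and heat shock genes, LIF, BMP, Nodal and FGF targets, TGF-beta and YAP targets, and imprinted genes. Further lists held markers of early endoderm, epiblast and mesendoderm, trophoblast and keratins, neural cells, muscle, macrophages and blood, endothelium and the 2-cell-like state, and Y-linked genes with Xist. Both lists of signalling targets also held pathway components, such as Tgfb1, Tgfbr2, Lifr, Fgfr1, Bmp4 and Nodal. Ribosomal protein and mitochondrially encoded genes were grouped by symbol after the data were seen. A member was measured with at least 20 reads over both types. Members at least 2-fold higher in either type were counted by size, and the list median was placed among the medians of 10000 random lists of the same size matched on mean expression. List medians were reported relative to the median of all genes with at least 100 reads.

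Cells were compared with the mean profile of each type, made without the cell itself, by Pearson correlation across genes of log2(CPM + 1) in genes with a mean of at least 10 CPM. They were also split into 2 clusters by k-means on 10 principal components. For detection and cell-to-cell variation each cell was thinned at random to 20000 gene reads, which left out 3 of the 45 ES cells and 0 MEFs. Variation was the squared coefficient of variation (CV) over the cells of a type, divided by the running median of the 100 genes nearest in mean, in genes with at least 50 CPM and reads in at least 20% of cells. Repeat reads were scaled like CPM, by the total of gene reads.

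Alternatives covered the scaling (mean of per-cell CPM, median-of-ratios, spike-in reads), the read minimum, thinning, pseudocounts of 1 and 10 CPM, plate rows A to D or E to H alone, the largest genes left out of totals, other correlations and filters, and each negative control well left out. Alternatives chosen after seeing the data were subtraction of the negative control background, removal of ES cell replicates 4, 7 and 30, wells with more gene than spike-in reads, uniquely mapped rows, ribosomal protein genes left out of totals, spike-ins 1 and 2 alone, spike-in and median-of-ratios scaling of repeats, and RLTR repeats without the ETn row that 2 families share.

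The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. The steps were tested on simulated data for the ES cell against MEF comparison. Counts for 13406 genes were drawn for both types from the MEF mean profile and the real well totals. In the simulated ES cells 200 genes, each with at least 200 expected ES cell reads, were changed 4-fold. Every gene was given the same CV over cells before counting. The spread of single genes in the real cells was not simulated, so the rates below hold for that setting only. Of the genes changed up 99% and of those changed down 100% were at least 2-fold the right way, with median log2 ratios of 2.02 and −2.04, while 1.51% of 10588 unchanged genes passed 2-fold. In the simulated lists, 20 changed genes reached percentiles 100 and 0, and 5% of 100 unchanged lists fell outside the central 95% of random medians. All 20 genes given one extreme cell led the variation ranking of 3280 genes, and 89 of 89 simulated cells lay nearest their own type, against 51 of 89 when both types were drawn from one profile.

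File positions did not match GRCm38, as 278 of 19273 gene rows on the same chromosome started within 10 bases of the GENCODE M21 position. Coordinates are therefore GRCm38 positions from GENCODE M21, found by gene symbol, and the file's own positions were not used.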

Results

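Single-cell transcript profiles were obtained from mouse ES cells of the R1 line, a pluripotent line grown from the early embryo, and from MEFs, adherent connective tissue cells of the mouse embryo. The series title sets out a characterisation of the transcriptional landscape of both cell types by multiplexed sequencing, so the design gives 1 comparison, ES cell against MEF, with the variation among cells inside each type. The plate held 48 ES cells, 44 MEFs and 4 negative control wells. ES cell wells with at least 10000 gene reads (45 of 48) held a median of 161206 gene reads (range 13576 to 703423), and the 44 MEF wells held 851801 (63938 to 1883709), 5.28 times as many. The negative control wells held 4356, 4662, 3273 and 236 gene reads, a median of 3814.5, which is 2.37% of the ES cell median and 0.448% of the MEF median.

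MEF wells gave far more gene reads per spike-in read than ES cell wells. Each type filled its own side of the plate. A difference in cellular RNA could therefore not be told apart from a difference between the plate sides. A median MEF well gave 152 gene reads per spike-in read (range 41.4 to 544) and a median ES cell well 6.62 (0.347 to 13.1), a 23-fold difference with no overlap, while negative control wells gave 0.126 (0.0246 to 0.196). More genes were also detected in MEFs, with a median of 5909.5 gene rows with a read against 2094 in ES cells and 637 in negative control wells. At an equal 20000 reads per cell, MEFs showed 3548 genes (n = 44, 0 left out) and ES cells 1511 (n = 42, 3 left out), 2.35 times as many in MEFs. Equal reads need not be equal molecules, as no molecular identifiers were mentioned. Ribosomal protein genes took a median of 46.1% of gene reads in ES cells and 14.2% in MEFs, which left fewer reads for other genes in ES cells. Of the kept wells, ES cell replicates 2, 7, 8 and 30 held more spike-in than gene reads. So did all 4 negative control wells and ES cell replicates 32, 44 and 46, which fell below the read minimum. Kept ES cell wells held more spike-in reads than MEF wells, with medians of 27100 and 4730. The makeup of the spike-in reads also differed, since spike-in 3 made up 31.7% of them in ES cells and 16.2% in MEFs.

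**Figure D1:**
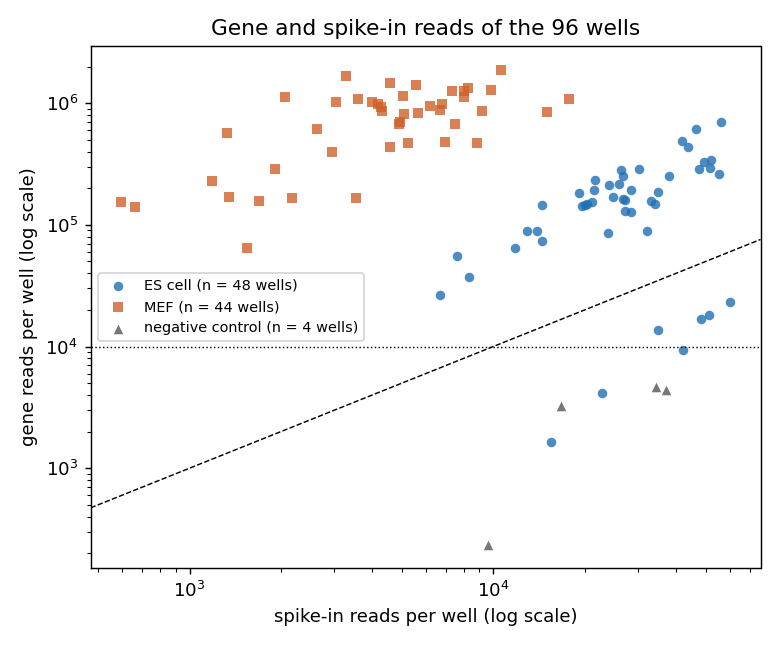
Gene reads against spike-in reads of the 96 wells on log axes, each point 1 well, with equal amounts on the dashed line and the minimum of 10000 gene reads on the dotted line. MEF wells (n = 44) lie at 41.4 or more gene reads per spike-in read, ES cell wells with the minimum at 13.1 or fewer, and the 4 negative control wells at 0.196 or fewer.

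Genes of the pluripotency network were higher in ES cells with 1 exception. Of 25 measured pluripotency genes, 24 were at least 2-fold higher in ES cells and 1, Klf4, was at least 2-fold higher in MEFs. The gene for the core pluripotency factor Oct4, Pou5f1 (chromosome 17, 35506018 to 35510772 on the plus strand, GRCm38), reached 731 CPM in ES cells (Poisson interval 713 to 749) and 2.59 CPM in MEFs (2.08 to 3.18). Dppa5a, a marker of undifferentiated cells (chromosome 9, 78367052 to 78368177, minus strand), reached 4816 against 17.4 CPM, and Sox2, the partner factor of Oct4, 386 against 2.90 CPM. Genes outside the list also led the ES cell side, among them Tdh, the threonine dehydrogenase on which mouse ES cells depend, at 1070.5 against 2.42 CPM, and Trh, the thyrotropin-releasing hormone precursor, at 605 against 1.19 CPM.

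Sizes are given relative to the median gene, because the 11054 genes with at least 100 reads had a median log2 ratio of −1.54 on the CPM scale (SD over plate rows 0.39), with 74.7% of them lower in ES cells. Counts of list members at least 2-fold higher in a type use the CPM scale. On that scale the median gene itself lay more than 2-fold lower in ES cells. This all-gene median was −0.26 under median-of-ratios scaling and −6.10 under spike-in scaling, so on the spike-in scale a gene stood higher in ES cells only where its relative ratio more than offset −6.10. The median pluripotency gene lay at a relative log2 ratio of 9.34 (SD over plate rows 1.12), above all 10000 random lists, and stayed higher in ES cells under every scaling tried. The 12 genes that led the ES cell side had relative log2 ratios from 7.78 (Pycard) to 11.39 (Lin28a). Among them, Pou5f1 was at 9.68, Dppa5a at 9.65, Sox2 at 8.59, Zfp42 at 8.98, Tcfcp2l1 at 9.34, Ifitm1 at 9.81, Apoe at 7.89 and Gm13242 at 9.45. Each of the 12 was higher in 8 of 8 plate rows. The naming rule had already asked for a 2-fold difference in rows A to D and E to H alone. Agreement over rows therefore follows partly from that rule. Thinned to 20000 reads, Lin28a was at 8.24, Ifitm1 at 7.83, Gm13242 at 8.13 and Zfp42 at 6.84, and with 10 CPM added the 12 lay between 5.34 (Pycard) and 8.14 (Dppa5a), with Lin28a at 5.53. In plate rows E to H alone Pycard was at 11.04 and Apoe at 10.14, and with background subtracted Dppa5a was at 10.91. Klf4 had 95.9 CPM in ES cells and 286 in MEFs, a CPM log2 ratio of −1.58 that lies at the all-gene median.

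The factors differed in how many ES cells held them at this depth. Pou5f1 had a read in 42 of 45 ES cells (93.3%) and 17 of 44 MEFs, and in 40 of 42 and 1 of 44 at an equal 20000 reads. Dppa5a had a read in 45 ES cells and in 42 of 44 MEFs, which fell to 10 of 44 MEFs at 20000 gene reads against 42 of 42 ES cells. Sox2 was read in 37 ES cells and 17 MEFs (34 of 42 and 1 of 44 thinned), and Lin28a in 19 and 2 (14 and 1 thinned). Nanog was read in 6 of 45 ES cells (5 of 42 thinned) with 364 reads in all and in 0 of 44 MEFs, at least 489-fold higher in ES cells against a floor of 3 reads. These shares rest on median depths of 161206 gene reads in ES cells and 851801 in MEFs, and Dppa5a, Zfp42 and Tdh had 43, 7 and 4 reads in the negative control wells.

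MEFs carried the programs of matrix-producing, contractile fibroblasts. All 25 measured extracellular matrix genes, all 18 mesenchymal identity genes and all 22 actin cytoskeleton genes were at least 2-fold higher in MEFs. So were 13 of 14 genes of the TGF-beta and YAP target list, the exception being the ligand gene Tgfb1. Fibronectin, Fn1 (chromosome 1, 71585520 to 71653200, minus strand), reached 14529 CPM in MEFs and 1009 in ES cells, and the matrix glycoprotein thrombospondin 1, Thbs1 (chromosome 2, 118111876 to 118127133, plus strand), 14041 against 664 CPM. The chains of collagen type I were at 1709 against 76.4 CPM for Col1a1 and 3627 against 199 CPM for Col1a2. Smooth muscle actin, Acta2, was at 2092 against 97.0 CPM, and the mesenchymal surface protein Thy1 at 332 against 12.7 CPM.

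Relative to the median gene, matrix genes had a median log2 ratio of −2.53 (SD over plate rows 0.76), mesenchymal genes −2.50 (SD 0.63), cytoskeletal genes −2.23 (SD 0.58) and TGF-beta and YAP targets −2.38 (SD 0.69), each at percentile 0 of random lists and lower in ES cells under every scaling tried. The 12 genes leading the MEF side ran from −3.66 for the fibril-associated collagen Col12a1 to −2.65 for Col1a2. Between them lay the matrix protease Mmp2 at −3.29, the hyaluronan receptor Cd44 at −3.16, Flrt2 at −3.09, Fam101b at −3.29, Col1a1 at −2.94, Acta2 at −2.89, Thbs1 at −2.86, Tagln at −2.83 and S100a6 at −2.70. Cxx1a (−3.65) had 13% unique reads, so most of its reads could also map elsewhere. Vimentin, Vim, was at −1.76, and the TGF-beta and YAP targets Amotl2, Igfbp7, Axl and Crim1 lay at −2.71, −2.54, −2.46 and −2.34.

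Matrix transcripts made up 5.43% of gene reads in MEFs, 0.326% in ES cells and 4.08% in the negative control wells, and pluripotency transcripts 0.0352%, 0.856% and 0.479%. Low-level matrix reads were thus also present in wells without a cell. Without ES cell replicates 4, 7 and 30, which lay nearer the MEF than the ES cell mean profile, the CPM log2 ratio of the median matrix gene was −4.30 in place of −4.07, and that of the median pluripotency gene 7.81 in place of 7.80.

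**Figure D2:**
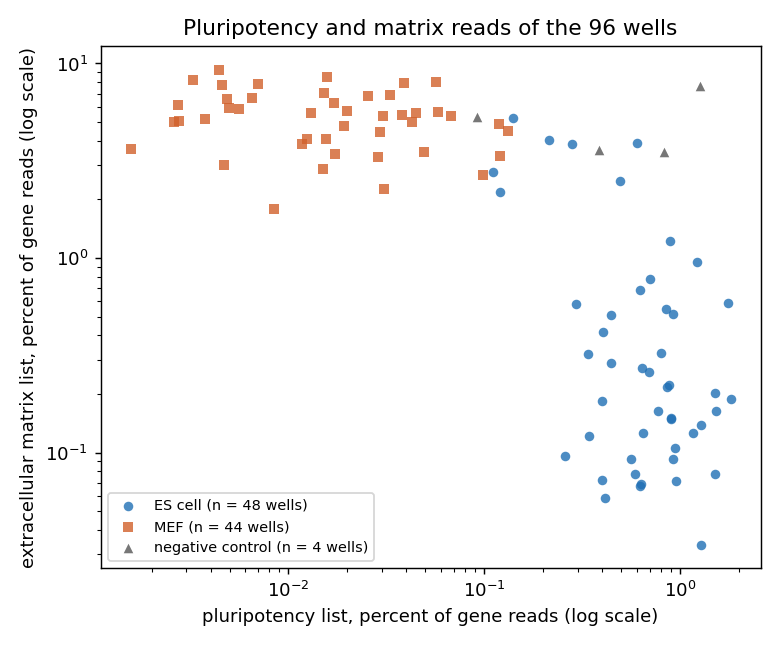
Pluripotency reads against extracellular matrix reads of the 96 wells, each as a percent of gene reads on log axes and each point 1 well (a well with 0 reads of a list is not drawn). Kept ES cells (n = 45) have a median of 0.691% pluripotency and 0.201% matrix reads, MEFs (n = 44) 0.0164% and 5.38%, and the 4 negative control wells 0.606% and 4.45%. The negative control wells thus lie among the MEF values for matrix reads only. Their median pluripotency share is above the highest MEF well (0.132%).

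Replication and mitosis genes stood above the median gene in ES cells, and inhibitors of the cell cycle stood below it. Of 19 S phase genes, 8 were at least 2-fold higher in ES cells, 3 (Rrm2, Cdc6 and Ccne2) at least 2-fold higher in MEFs, and 8 neither. These counts were 3 against 6 in plate rows A to D, 15 against 2 in rows E to H, 14 against 2 under median-of-ratios scaling and 0 against 19 under spike-in scaling. The helicase subunit Mcm7 had 124 against 33.8 CPM, Mcm3 84.4 against 20.5 CPM and the flap endonuclease Fen1 34.9 against 8.45 CPM, whereas the ribonucleotide reductase subunit Rrm2 had 24.8 against 119 CPM. Of 18 G2 and M phase genes, 7 were at least 2-fold higher in ES cells, 0 in MEFs and 11 neither, with cyclin B1, Ccnb1, at 180.5 against 41.5 CPM, Kif11 at 94.9 against 19.5, Bub1 at 144 against 41.8 and Ccna2 at 105 against 27.7. Their counts were 3 against 3 in rows A to D, 18 against 0 in rows E to H, 16 against 0 under median-of-ratios and 0 against 18 under spike-in scaling. Among 12 inhibitors and growth arrest genes, 11 were at least 2-fold higher in MEFs and 1, Cdkn1b, was neither, with the p53 target Cdkn1a at 1304 against 116 CPM in ES cells, Btg2 at 195 against 11.9, Cdkn2b at 131 against 11.6 and Ccng1 at 1089 against 221.

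The median relative log2 ratio was 2.34 for S phase (SD over plate rows 1.48, percentile 99.99), and its CPM median of 0.80 became −3.77 under spike-in scaling. For G2 and M phase it was 2.35, smaller than its SD over plate rows of 2.89, with a CPM median of −0.09 in rows A to D, 4.81 in rows E to H and −3.75 under spike-in scaling. Of the 12 inhibitors and growth arrest genes, 8 lay at least 2-fold below the median gene and 1 at least 2-fold above it. Inhibitors lay at −1.34 (SD 0.84, percentile 2.15) and were lower in ES cells under every scaling tried. Single genes of this group spread widely over plate rows, with an SD of 3.68 for Ccnb1, 3.40 for Rrm2 and 0.94 for Cdkn1a.

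The DNA methylation and Polycomb list had a higher median ratio of ES cell over MEF than all genes. It also held other chromatin regulators, namely Chd1, Trim28, Smarca4, Smarcc1, Kdm1a and Hdac1. Of 16 measured, 7 were at least 2-fold higher in ES cells (Dnmt3b, Uhrf1, Tet1, Tet2, Suz12, Eed and Jarid2), 1 (Kdm1a) at least 2-fold higher in MEFs and 8 neither. Tet1, which oxidises methylcytosine (chromosome 10, 62804570 to 62908996, minus strand), had 532 against 11.9 CPM, Uhrf1, which recruits the maintenance methyltransferase, 213 against 24.5 CPM, and the Polycomb cofactor Jarid2 45.1 against 0.740 CPM. The relative log2 ratio of Jarid2, 7.47 (SD 2.84), was 4.39 when thinned, 3.04 with 10 CPM added and 11.68 in plate rows A to D. Eed, a core subunit of the same complex, had 142 against 42.5 CPM. The list had a median relative log2 ratio of 2.14 (SD 0.98, percentile 99.78), and its CPM median of 0.60 became −3.96 under spike-in scaling.

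Glycolytic genes went both ways on the CPM scale. Gapdh (chromosome 6, 125161715 to 125166467, minus strand) had 2059 CPM in ES cells and 123 in MEFs and was higher in 8 of 8 plate rows (SD 0.61), Ldhb 528 against 52.7 CPM and Pfkp 134 against 32.4 CPM, whereas the hexokinase Hk1 had 28.8 against 326 CPM. Under spike-in scaling Gapdh, Ldhb and Pfkp, with relative log2 ratios of 5.60, 4.87 and 3.59, lay lower in ES cells. Of 15 members, 4 were at least 2-fold higher in ES cells, 3 in MEFs and 8 neither, with a median relative log2 ratio of 1.06 (SD 0.82, percentile 74.2). Set against the median gene, 8 members were at least 2-fold above and 1 at least 2-fold below. The CPM median of the list, −0.48, turned to 0.80 under median-of-ratios scaling and to 0.16 with ribosomal protein genes left out of totals.

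Stress genes did not stand apart from random lists, and the genes listed for LIF, BMP, Nodal and FGF signalling went both ways. Of 15 immediate early and heat shock genes, 13 were at least 2-fold higher in MEFs and 2 (Ier2 and Hspb1) neither, with heme oxygenase, Hmox1, at 1688 CPM against 144 in ES cells, Ier3 at 140 against 13.1, Dusp1 at 113 against 8.26 and Dnajb1 at 61.8 against 7.57. Set against the median gene, 7 of the 15 were at least 2-fold below and 1 at least 2-fold above. That list had a median relative log2 ratio of −0.85, smaller than its SD of 1.11 (percentile 8.69), and Hmox1 had an SD of 3.0 over plate rows. Among 16 LIF, BMP, Nodal and FGF targets, 5 were at least 2-fold higher in ES cells (Socs3, Lefty1, Lefty2, Nodal and Fgfbp1), 8 in MEFs and 3 neither. The Nodal inhibitors Lefty2 and Lefty1 had 108 and 105 CPM in ES cells against 0.228 and 2.22 CPM in MEFs, relative log2 ratios of 10.44 and 7.10 that were 4.21 and 3.91 with 10 CPM added, and 6.49 for Lefty2 when thinned. The BMP targets Id3 and Id2 had 379 and 80.2 CPM in MEFs against 25.9 and 5.62 in ES cells. Of the 16 LIF, BMP, Nodal and FGF targets, 7 lay at least 2-fold above the median gene and 4 at least 2-fold below it. The median of that list was 0.63 above the median gene, less than its SD of 0.73 (percentile 74.6), and its CPM median of −0.91 turned to 0.37 under median-of-ratios scaling.

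Imprinted genes mostly had higher CPM in MEFs. Of 20 measured, 15 were at least 2-fold higher in MEFs, 2 (Peg10 and Phlda2) in ES cells and 3 (Snrpn, Mirg and Airn) neither. Set against the median gene, 10 were at least 2-fold below and 4 at least 2-fold above. The growth factor gene Igf2 had 855 CPM in MEFs and 60.5 in ES cells, and its neighbour H19, a noncoding RNA, 559 against 39.3 CPM. The receptor Igf2r had 392 against 28.6 CPM and Ndn 257 against 18.8 CPM. The list had a median relative log2 ratio of −1.35 (SD 0.74, percentile 1.05) and was lower in ES cells under every scaling tried, while Igf2 and H19 had SDs of 2.80 and 2.32 over plate rows.

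Most markers of other lineages had too few reads in both cell types to be measured. Of 16 early endoderm genes 7 were measured, with 1 (Lama1) at least 2-fold higher in ES cells and 4 in MEFs, and Dab2 had 153 CPM in MEFs against 4.13 in ES cells. Gata6 had 743 reads in MEFs and 2 in ES cells, and Lama1 183 reads in ES cells and 3 in MEFs. Of 10 epiblast and mesendoderm genes 4 were measured, and Otx2 had 561 reads in 8 of 45 ES cells (8 of 42 thinned) and 3 reads in 2 of 44 MEFs (0 of 44 thinned). Foxd3 was also at least 2-fold higher in ES cells, and Eomes and Gsc in MEFs, with 40, 0 and 2 ES cell reads against 6, 153 and 165 MEF reads.

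Of 6 measured trophoblast and keratin genes 4 were at least 2-fold higher in MEFs, led by Gata3 at 40.6 against 1.72 CPM and Krt19 at 16.9 against 1.83 CPM, and Krt8 had 20 reads in 1 ES cell and 0 in MEFs. Of 5 measured neural genes, Stmn2 had 371 CPM in ES cells against 72.4 in MEFs, and Nes and Tubb3 had 133 and 69.7 CPM in MEFs against 12.5 and 14 in ES cells. Among 6 muscle genes 3 were at least 2-fold higher in each type, with Acta1 at 22.3 CPM in MEFs against 0.917 in ES cells and Ttn at 60 reads in 2 ES cells against 0 in MEFs. Macrophage and blood genes had 3 measured members, of which Lyz2 and Csf1r had 74 and 23 MEF reads, and endothelial genes 4, with Egfl7 at 37.4 CPM in ES cells against 5.23 in MEFs and Kdr and Flt1 at 200 and 545 MEF reads against 0 and 9. The 11 genes of the 2-cell-like state found in the table, Zscan4c among them, had 0 reads in both types, which allows up to 0.344 CPM in ES cells and 0.0853 CPM in MEFs.

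None of these lineage lists stood apart from random lists. Their median relative log2 ratios were −0.87 for early endoderm (percentile 22), 2.08 for epiblast and mesendoderm (87.6), −1.81 for trophoblast and keratins (6.65), −0.41 for neural (37.9), 1.32 for muscle (89.6), 0.61 for macrophage and blood (86.4) and −0.80 for endothelial genes (33.9). The CPM median of the epiblast list, 0.54, became −4.02 under spike-in scaling, and those of the muscle (−0.22) and macrophage lists (−0.93) became 1.06 and 0.36 under median-of-ratios scaling.

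Xist and Y-linked genes were each read in only part of the MEFs. Xist, the noncoding RNA that silences one X chromosome in female cells, had 128 CPM in MEFs and 4.70 in ES cells, and was read in 25 of 44 MEFs and 10 of 45 ES cells (20 of 44 and 3 of 42 thinned). The Y-linked gene Kdm5d had 773 reads in MEFs and 1 in ES cells, and Ddx3y 47.2 CPM in MEFs and 24.5 in ES cells. Tsix, the antisense partner of Xist, had 17.8 CPM in ES cells and 0.768 in MEFs, and the strand-keeping protocol counts it apart from Xist. Of 6 members 1 (Tsix) was at least 2-fold higher in ES cells, 2 (Kdm5d and Xist) in MEFs and 3 neither, with a median relative log2 ratio of 0.66 (SD 1.36, percentile 68.7) and a CPM median of −0.88 that turned to 0.40 under median-of-ratios scaling.

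**Figure D3:**
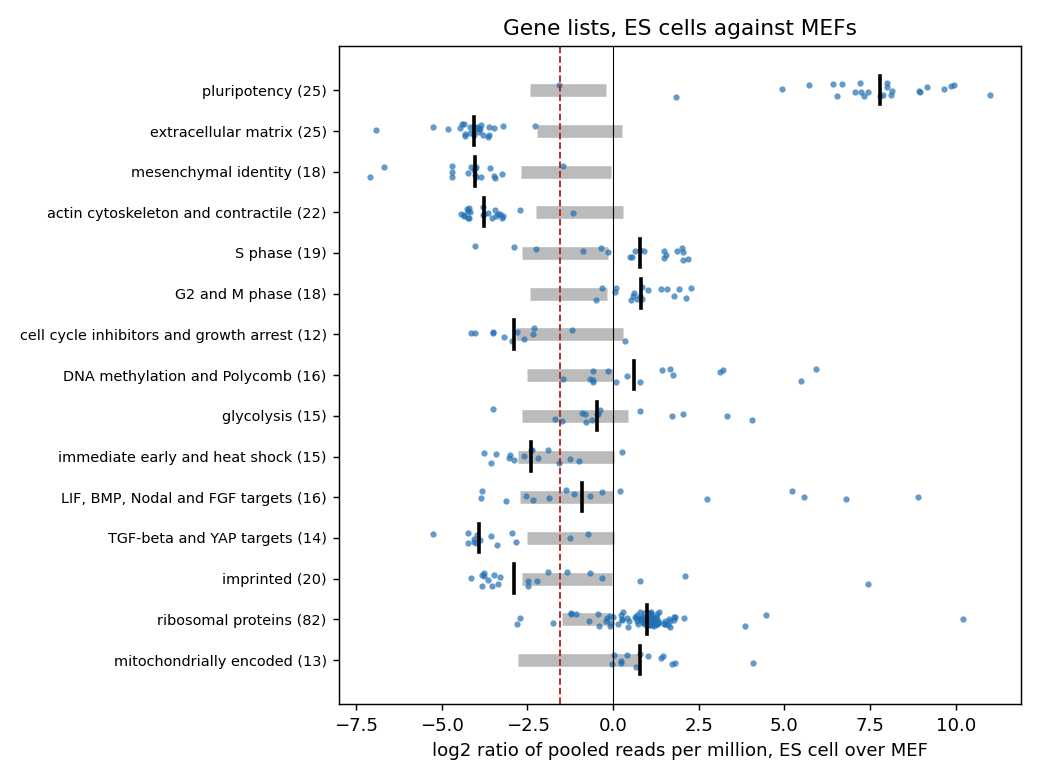
Log2 ratio of pooled CPM, ES cell over MEF, of the members of 15 gene lists (points, measured number in brackets), with the list median (black bar), the central 95% of the medians of 10000 matched random lists (grey) and the all-gene median of −1.54 (dashed line). Pluripotency genes have a median of 7.80 and extracellular matrix genes −4.07; under spike-in scaling the S phase, G2 and M phase, DNA methylation, ribosomal and mitochondrial medians turn negative, and under median-of-ratios scaling those of glycolysis and LIF, BMP, Nodal and FGF targets turn positive.

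Transcripts of the translation machinery and of mitochondria took a larger share of reads in ES cells. The 83 ribosomal protein genes made up a median of 46.1% of gene reads in ES cells, 14.2% in MEFs and 16.7% in negative control wells. A single gene, Rpl4, which encodes a protein of the large ribosomal subunit, made up a median of 18.7% of gene reads in ES cells (range 0.696 to 31.4%) and 0.845% in MEFs (at most 2.99%), and was the most read gene in 43 of 45 ES cells and 6 of 44 MEFs. Of the 82 measured ribosomal protein genes, 40 were at least 2-fold higher in ES cells, 6 in MEFs and 36 neither, with a median relative log2 ratio of 2.53 (SD 0.61, percentile 100). Of the 13 mitochondrially encoded genes, 6 were at least 2-fold higher in ES cells, 0 in MEFs and 7 neither, with a median of 2.34 (SD 0.90, percentile 98.4). The CPM medians of both families, 0.99 and 0.80, became −3.57 and −3.76 under spike-in scaling.

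Most cells lay nearest the mean profile of their own type. Over 7808 genes, 42 of 45 ES cells (93.3%, exact binomial interval 81.7 to 98.6%) and 44 of 44 MEFs correlated best with their own type, and ES cell replicates 4, 7 and 30 were closer to the MEF mean. Without the labels, k-means placed 41 of 45 ES cells and 43 of 44 MEFs in the cluster of their type, all but ES cell replicates 4, 10, 22 and 26 and MEF replicate 53. These ES cells held 4755, 4864, 6143 and 3873 genes, above the ES cell median of 2094. MEF replicate 53 held 1395 genes, the fewest of any MEF. ES cell replicates 21, 41 and 47, with 4267, 4056 and 4831 genes, stayed with their type. The split may thus partly follow the number of genes detected, which was not tested. The first principal component held 24.7% of the variance and the second 2.92%. The median correlation across genes was 0.443 between ES cells, 0.609 between MEFs and 0.404 between types, and since depth differed between types these values also carry sampling noise. Leaving out the pluripotency, matrix, mesenchymal and cytoskeleton genes left 86 of 89 cells nearest their own type, and k-means then placed ES cell replicates 4 and 22 and MEF replicates 53, 62 and 80 with the other type.

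**Figure D4:**
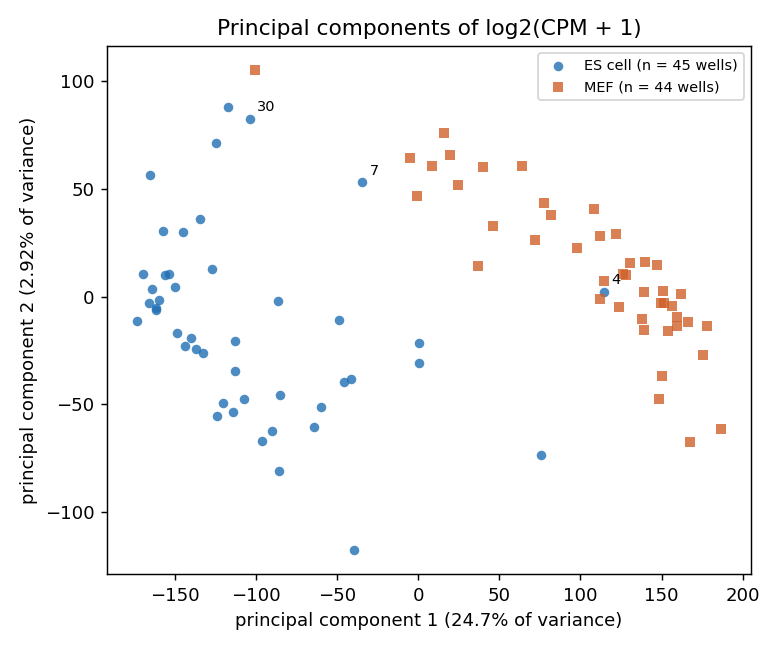
First against second principal component of log2(CPM + 1), each point 1 cell (45 ES cells, 44 MEFs), with ES cell replicates 4, 7 and 30 marked by number. ES cells and MEFs separate along the first component (24.7% of variance), apart from a few cells, among them ES cell replicate 4, which lies among the MEFs. The types also differ in genes detected, with medians of 2094 in ES cells and 5909.5 in MEFs.

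Several of the genes ranked as most variable within a type had most of their reads in 1 cell, a pattern that this ranking favours. In ES cells the 8 genes that varied most beyond genes of like abundance included Rdx, Hnrnpd, Bend4, Tmem64, Frs3, Lmnb1 and Stoml2, and in MEFs they were Snrpa, Ntf3, Sort1, Nfx1, Dyrk1a, Igfbp3, Prdm2 and Myadm. The cytoskeletal linker Rdx, at a CV of 5.38, had 82.3% of its thinned ES cell reads in replicate 13. The splicing protein gene Snrpa had 84.9% of its MEF reads in replicate 83, whereas Myadm, with reads in 44 of 44 MEFs, had 39.8% in replicate 50. With the highest cell of each gene left out, 2 of the 8 ES cell genes (Rdx and Bend4) and 1 of the 8 MEF genes (Sort1) stayed among the 8 most variable. Over the 1286 genes measured in both types, the median CV was 1.81 in ES cells and 1.11 in MEFs at 20000 gene reads per cell. Total gene reads were matched, but not the larger share of them that ribosomal protein genes took in ES cells. As the technical spread, the abundant spike-ins 1 and 2 had CVs of 0.180 and 0.161 in ES cells and 0.208 and 0.210 in MEFs, as shares of spike-in reads without thinning. Spike-in 3, at 31.7% of spike-in reads in ES cells and 16.2% in MEFs, had CVs of 0.247 and 0.586. The less abundant spike-ins 4 to 8 ranged from 0.473 to 4.86 in ES cells and from 0.634 to 5.75 in MEFs. The technical spread of less abundant RNA thus reached the size of the gene CVs.

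Retroviral elements of the ETn and MusD families were transcribed far more in ES cells. Scaled by gene reads, their log2 ratio was 5.61 (SD over plate rows 0.79, higher in 8 of 8 rows) and stayed positive, at 1.05, under spike-in scaling. The ETn long terminal repeat RLTRETN_Mm was 113-fold and the internal part MMETn-int 49.6-fold higher in ES cells, and the named long terminal repeats LTRIS2 and LTRIS3 were 158-fold and 271-fold higher. RLTR27, RLTR9E, RLTR17 and RLTR1B-int were 51, 32.4, 25.5 and 21.2-fold higher, of which RLTR1B-int turned to a log2 ratio of −0.16 under spike-in scaling. All repeats together made up 24.3% of gene and repeat reads in ES cells, 12.1% in MEFs and 65.2% in the negative control wells.

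The other families with a clear excess in ES cells on the gene-read scale were lower there under spike-in scaling. RLTR elements had a log2 ratio of 2.37 (SD 0.41; −2.20 under spike-in scaling), but they include RLTRETN_Mm, which is also counted among ETn elements, and without it they had 1.14 (SD 0.51; −3.42). L1 elements had 1.71 (SD 0.49; −2.85), B2 1.61 (SD 0.60; −2.95), B1 0.60 (SD 0.39; −3.96) and all repeats 1.22 (SD 0.35; −3.34). Satellite (0.57, SD 1.31), IAP (0.23, SD 0.64), MERVL and MT2 (0.26, SD 0.78) and rRNA (−0.80, SD 1.28) differed by less than the SD over plate rows on that scale, and rRNA turned to 0.48 under median-of-ratios scaling while the others became −3.99, −4.33 and −4.30 under spike-in scaling. L1 made up 50.9% of repeat reads in the negative control wells, 15.4% in ES cells and 10.9% in MEFs.

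**Figure D5:**
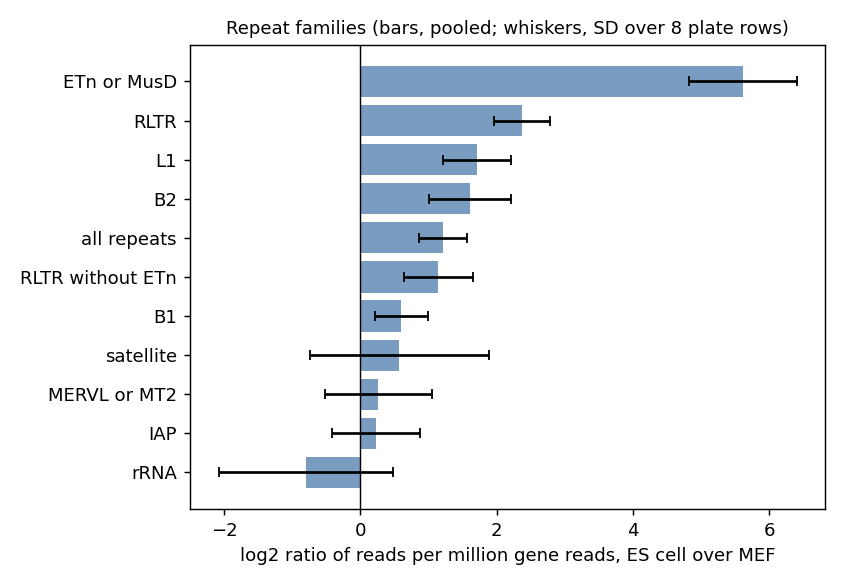
Log2 ratio of repeat reads per gene read, ES cell over MEF, for 9 repeat families, RLTR without the ETn row it shares with ETn or MusD, and all repeats (bars, pooled reads; whiskers, SD over 8 plate rows). ETn or MusD elements reach 5.61 and stay positive under spike-in scaling (1.05), while every other bar lies below 0 on that scale, such as RLTR without ETn at −3.42 and L1 at −2.85.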

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

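More gene reads than in any negative control well appeared in 1 well that the comparisons did not use, and no explanation, technical or biological, was tested for it. ES cell replicate 44, left out because it lay under the minimum of 10000 gene reads, held 9327 gene reads, above the 4662 of the highest negative control well. It gave 0.222 gene reads per spike-in read, against at most 0.196 in the negative control wells, a gap smaller than the SD of 0.0708 over those wells, and its profile correlated at 0.479 with the ES cell mean and 0.457 with the MEF mean. The negative control wells also lay nearer the ES cell mean (0.221 to 0.445, against 0.184 to 0.431 with the MEF mean), so these correlations do not tell a cell from background. Rpl4 made up 0.600% and matrix genes 4.04% of its reads. The other wells left out, ES cell replicates 32 and 46, held 4136 and 1641 gene reads, inside the range of the negative control wells. The lowest negative control well, replicate 96, held 236 gene reads and 79 genes, against 3273 to 4662 gene reads and 596 to 852 genes in the other 3.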

How the results depend on the processing

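The tests without ES cell replicates 4, 7 and 30, with background subtracted, with uniquely mapped genes, with gene-rich wells, without ribosomal protein genes in totals and with spike-ins 1 and 2, as well as both other scalings of repeats and RLTR without its ETn row, were chosen after the results were seen. List and gene values are relative to the all-gene median, so scalings by 1 factor per type and genes left out of totals leave them as they were by construction. Over the alternatives that could move them, 253 list values, 1145 gene values and 121 repeat values kept their direction within 1 SD over plate rows, 10, 71 and 19 moved further, and 12, 30 and 12 reversed. The 12 leading genes of each type were chosen partly on per-cell CPM and on plate rows A to D and E to H. Their agreement under those alternatives was therefore partly set by the naming rule. The MEF over ES cell ratio of genes detected ranged from 1.84 to 2.82, and that of gene reads per spike-in read from 17.1 to 23.6. Under the alternatives, 1 to 5 cells lay nearer the other type, and k-means put 5 or 6 with the other type. Samples were not paired, as replicate numbers were unique across the plate, and ratios within each plate row gave the SD. The cause of the shifts below was not tested, except where stated.

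The all-gene median of −1.54 became −0.26 under median-of-ratios scaling, −6.10 under spike-in scaling, −1.05 at 20000 reads, −0.68 with 10 CPM added, which shrinks low genes by construction, and −0.90 without ribosomal protein genes in totals. Negative control reads were 1.33% of the median cell, 1.14 to 1.52% with each negative control well left out, and 17.4% by genes detected. The ratio of median CVs, 1.63, became 1.86 without thinning, where ES cells keep their lower depth, and was 1.57 to 1.66 under the 4 others.

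Main list values were 9.34 for pluripotency, 2.34 for S phase, 2.35 for G2 and M phase, −2.38 for TGF-beta and YAP targets, 2.08 for epiblast, 1.32 for muscle, 0.61 for macrophage and blood, −0.41 for neural, −0.80 for endothelial, −0.87 for early endoderm and −1.81 for trophoblast genes. The first 4 kept their direction under all alternatives that could move them.

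Thinning took the pluripotency median to 5.57. Of its 25 genes 13 had 0 thinned MEF reads and so took the floor, with a median of 4.48 in place of 9.53, and the others had 7.46 in place of 8.88. It also took early endoderm to 0.12, trophoblast to 0.031 and endothelial genes to 0.98, and Gsc to 2.70, Eomes and Krt7 to 1.12, Krt18 and Kdr to 0.70, Tnnt2 to 0.38, Flt1 to 0.85, Ddx3y to −0.11, Nfx1 to −1.84 and Prdm2 to −1.14. The mean of per-cell CPM gave −1.56 for TGF-beta and YAP targets, 0.98 for endothelial genes, 0.90 for Flt1, −0.29 for Ddx3y, −1.15 for Nfx1 and −1.13 for Prdm2. Adding 10 CPM gave 0.15 for Gsc, 0.16 for Eomes, 0.17 for Krt18, 0.27 for Tnnt2, 0.028 for Kdr, −0.049 for Ddx3y and −0.63 for Nfx1, and adding 1 CPM −0.075 for Nfx1.

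In plate rows A to D, early endoderm and Lamb1-1 were at 0.13, epiblast at 6.91, neural at 2.97, macrophage and blood at 3.19, Tmem64 at −0.58 and Dyrk1a at 0.95. In rows E to H, S phase was at 3.86, G2 and M phase at 6.42, muscle at 4.88, trophoblast at −0.32, endothelial at 0.33, Rrm2 at 0.33, Tnnt2 at 2.46, Igfbp3 at 0.16, Nfx1 at −1.12 and Prdm2 at −0.42, and MERVL and MT2 repeats turned to −0.13. With members of at least 1 read, early endoderm was at 0.015, neural at 1.14, endothelial at 1.66 and macrophage and blood at 2.58. With at least 100 reads, epiblast was at −2.12, muscle at −2.39 and endothelial at −2.37, and macrophage and blood had no member left. At this depth the 7 lineage lists had 3 to 7 measured members.

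Each of these single-gene values reversed its main value. Other named genes kept their sign but shifted by more than their SD over plate rows. Thinning gave 4.23 for Nanog (main value 10.47), 6.04 for Otx2 (11.10), 4.62 for Lama1 (9.48), 4.94 for Gapdh (5.60), −2.97 for Gata6 (−4.99), −1.62 for Gata3 (−3.02), −1.26 for Acta1 (−3.06) and −2.79 for Kdm5d (−6.04). Adding 10 CPM gave these genes 3.05, 3.56, 2.30, 4.64, −0.93, −1.43, −0.89 and −0.98, Tdh 7.12 (10.33), Trh 6.46 (10.52), Ldhb 3.78 (4.87), Tsix 2.04 (6.07), Vim −2.58 (−1.76) and Ccng1 −1.57 (−0.76). Adding 1 CPM gave Nanog 6.81, Otx2 7.30, Lama1 5.73, Lefty2 7.87, Gata6 −2.78, Gsc −0.82 and Kdm5d −2.97. Rows A to D gave Nanog 7.61, Tsix 8.62, Gata6 −3.42, Gsc −0.93 and Kdr −1.15, and rows E to H Mcm3 9.02 (3.58), Ccnb1 7.45 (3.66), Kif11 9.51 (3.83), Ccna2 9.73 (3.46), Tsix 3.59, Nes −4.58 (−1.87), Krt18 −0.60 and Kdm5d −3.63. The mean of per-cell CPM gave Acta1 −1.82, Xist −2.33 (−3.23) and Hnrnpd 4.89 (2.86). Without ES cell replicates 4, 7 and 30 Acta1 was at −5.02 and Flt1 at −4.50 (−2.37), and Flt1 was at −4.48 with at least 50000 gene reads and −4.51 in gene-rich wells.

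All repeats, RLTR, L1, B2 and ETn or MusD were at 1.22, 2.37, 1.71, 1.61 and 5.61 per gene read. RLTR without the row it shares with ETn was at 1.14, −3.42 under spike-in and 2.43 under median-of-ratios scaling. Under spike-in scaling repeats turned to −3.34 (all), −2.20 (RLTR), −2.85 (L1), −2.95 (B2), −3.96 (B1), −3.99 (satellite), −4.33 (IAP), −4.30 (MERVL and MT2) and −0.16 (RLTR1B-int), and ETn or MusD kept 1.05. Under median-of-ratios scaling they were 2.5, 3.65, 2.99 and 2.89 for the first 4 and 6.89 for ETn or MusD, and rRNA turned to 0.48. Of the 8 most variable genes, 2 to 5 in ES cells and 1 to 8 in MEFs were again among the 8 most variable, with 2 and 1 when the highest cell of each gene was left out.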

Other observations

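All tests in this part were chosen after the result was seen, apart from that of the Rpl4 share against the amount of RNA. The genes named in this paragraph were chosen after their values were seen. The orphan receptor gene Esrrb had 803 reads in 20 of 45 ES cells and 4 reads in 2 of 44 MEFs, and the Nodal coreceptor gene Tdgf1 237 against 0.939 CPM. Rpl10l, a relative of the ribosomal protein gene Rpl10, had 296 reads in 10 ES cells and 1 read in 1 MEF.

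The MEFs may come from embryos of both sexes. With limits of 30 and 10 reads chosen after seeing the data, 19 of 44 MEF wells held at least 30 Xist reads and fewer than 10 Y-linked reads, 15 held the reverse, and 9 neither. Only 1 MEF well, replicate 58, held at least 30 of each (909 Xist and 37 Y-linked reads), where 7.27 would be expected if both were independent (20 wells high in Xist, 16 in Y-linked genes). At least 1 read of each was held by 12 of 44 MEF wells, while 13 held Xist alone, 17 Y-linked reads alone and 2 neither. The near absence of wells with both was thus seen at the limit of 30 reads, not at 1 read. Among ES cells, 7 of 45 held at least 30 Y-linked reads and 0 of 45 held as many Xist reads (exact binomial interval up to 7.87%), at a lower depth than in MEFs. No technical explanation was tested for this split.

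ES cell wells held reads of matrix genes, and the test set 3 sources against each other. Background at the level of the negative control wells is argued against, since 33 of 45 ES cell wells (73.3%, exact binomial interval 58.1 to 85.4%) held more matrix reads than the highest negative control well (174 reads), with medians of 366 in ES cells and 38246.5 in MEFs. All negative control wells lay on the MEF side of the plate. A higher background on the ES cell side was not measured and stays open. RNA or reads from the MEFs of the plate may be a source, because 1 source keeps 1 ratio, and the SD of the log2 ratio over matrix genes, 0.811, lay at percentile 0.16 of matched lists of genes at least 2-fold lower in ES cells. Matrix genes were listed for a shared function, which the random lists do not have. The percentile therefore cannot decide between this source and expression by the ES cells. This test replaced one against lists from all genes (percentile 0), which mix directions. Cytoskeletal genes lay at percentile 0.04, but mesenchymal genes at 41, so the small spread did not extend to every MEF list. The CPM list medians themselves lay close together, at −4.07 for matrix, −4.04 for mesenchymal and −3.77 for cytoskeletal genes, and this likeness was not tested. MEF-like cells among the ES cells would also keep 1 ratio and stay open, as does expression shared by all matrix genes in ES cells.

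ES cell replicates 4, 7 and 30 lay nearer the MEF mean profile (correlations with the MEF and ES cell means of 0.62 and 0.47, 0.529 and 0.507, and 0.489 and 0.484). Replicate 30 lay nearer the ES cell mean with no CPM minimum or no minimum of gene reads, nearer the MEF mean under 3 other alternatives, and k-means put replicate 7 with the MEFs when thinned or with a mean of at least 50 CPM. Background at the level of the negative control wells is argued against, as replicates 4, 7 and 30 gave at least 0.354 gene reads per spike-in read against at most 0.196 (SD 0.0708), but replicate 7 had the composition of those control wells (Rpl4 0.696%, ribosomal 20.3% and matrix 3.85% of reads, against medians of 0.771, 16.7 and 4.45%), so a larger amount of such background stays open for it. The control wells lay on the MEF side of the plate, so background on the ES cell side was not measured. Replicate 4, with 4755 genes and an Rpl4 share of 1.07%, held 5 Xist and 14 Y-linked reads, and although 0 of 44 MEF wells thinned to its depth held as many of both, 5 other ES cell wells also held both, so this leaves RNA of more than 1 MEF undecided. Replicate 30 had Rpl4 at 30.4%, ribosomal protein genes at 44.3% and pluripotency genes at 0.495% of reads, above the highest MEF wells at 2.99, 25.5 and 0.132%. These shares argue against a MEF alone in that well, unless the plate side changed them. No biological explanation was tested, and an ES cell with added MEF RNA stays open. A MEF in the wells of replicates 4 and 7 also stays open, since at most 7.23 gene reads per spike-in read against 41.4 in the lowest MEF well may reflect the plate side.

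Rpl4 took 39.8% of ribosomal protein reads in ES cells and 8.44% in MEFs, and without it ribosomal protein genes still made up 27.4% and 13.6% of gene reads. Reads shared with other copies are argued against, since 99.9999% of Rpl4 reads were uniquely mapped, and so are a few wells with extreme amplification, since 95.6% of ES cell wells (43 of 45, interval 84.9 to 99.5%) lay above the highest MEF well at 2.99%. Whether a small amount of RNA raises the share stays undecided, because wells under the median of gene reads per spike-in read had 1.07 times the share of those above it in ES cells and 1.18 times in MEFs, between the sizes set beforehand for and against it. A difference between the cell types, or between the sides of the plate that held them, stays open and untested.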
